A study of Mus musculus with 2 samples.

How the data were processed

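Hdac1 and Hdac2 ChIP-seq of nephron progenitor cells from E16.5 mouse kidneys was analysed from 2 deposited island lists, 1 per antibody. Per the labels' protocols, each library was made from 500 pg of DNA, and libraries were amplified for 12 cycles plus 1 to 3 further cycles until the yield was enough. Such amplification makes reads that are not independent molecules. The file labels give 0.5 µg of antibody for Hdac1 and 1 µg for Hdac2, so antibody and amount changed together. Control immunoprecipitations with IgG and with an antibody against H3K4me3 were run in parallel, per the labels, and were not analysed here.

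Per the submitters' processing notes, the tools were FastQC, BWA 0.7.5a, SAMtools 1.3.1, bedtools 2.17 and SICER, with build mm10. SICER joins neighbouring windows with more reads than background into islands, which suits broad signal and gives wide regions with coarse edges. Its version and settings, the background library, the read depth, and whether reads were pooled are not given in the sources used here. The deposited lists give for each island a position and 1 value, a p-value or q-value of the authors, and nothing states which; all values were below 0.1. Island starts and widths were multiples of 200 bp, and the closest islands were 800 bp apart. Starts and ends in the files count from 0, with the end being the last base of the island, and positions are given 1-based.

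Genes came from the RefSeq annotation of GRCm38.p6, the same assembly as mm10, and 21883 protein-coding genes on chromosomes 1 to 19, X and Y were tested. That table has gene spans without strand, exons or sequence. The planned promoter, 1 kb either side of the transcription start, was therefore replaced by 1 kb either side of each gene end, and some islands counted at a gene lie at its 3′ end. Of the 13283 Hdac1 genes 1959 had islands at both ends. For the same reason islands were not split into exon and intron, random placements did not leave out assembly gaps or keep GC content, random gene lists were matched on decile of gene length in place of CpG content, and the planned comparison of sequence motifs was not run. Some genes have positions at the very start of a chromosome, from base 194 on chromosome 1 and base 7 on chromosome 4. On chromosome 2 the first gene or island starts at base 3078201. The first genes on chromosome 1 had no island within 100 kb. Whether such positions lie on assembled sequence was not checked, and these genes stayed in all counts, random sets and placement ranges.

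Overlap of islands meant at least 1 bp shared. Islands were placed at random within the range of genes and islands on their own chromosome, with bedtools 2.31.1 shuffle, 1000 times for whole lists and 200 times for parts of lists. Islands without the other antibody were placed 200 times on sequence free of the other antibody's islands, since selecting them removes gene ends where the other antibody lies; this was chosen after the results were seen. For each gene list the number of genes with an island was set beside 10000 random lists of the same size matched on gene length decile, and its percentile was recorded as a description of the library, with ties shared equally between above and below. For Hdac2 a second set of random lists was drawn from genes with an Hdac1 island, matched on decile of that island's value; this was chosen after the results were seen. Where a gene had several islands at its ends, the one with the lowest value was given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Intervals of shares are 95% Wilson intervals.

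The 14 gene lists, with 328 genes, were fixed before the data were examined, and 327 genes were in the annotation as protein-coding. Hotairm1 was left out. Individual results of some listed genes are not reported here. Named genes are members of these lists, the 10 genes with the strongest islands in each library (lowest value, then width, then symbol, 1 gene per island) and the 5 strongest genes with an island in 1 library only.

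The steps were tested on simulated data before use. Overlap counts equalled those of bedtools for random lists the size of each library. All 200 genes given an island at an end were recovered in each simulated library of 21883 genes. A planted list of 30 genes reached percentile 100, and of 100 unplanted lists 7 fell outside the central 95% for the simulated Hdac1 library and 3 for Hdac2.

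Alternatives were a stricter list (upper 50% of islands by value), other definitions of overlap, equal list lengths, other windows at gene ends, islands merged within 1 kb, leaving out chromosome Y, and unmatched random lists. Added after the results were seen were lists shifted as a whole, islands up to 20 kb only, matching on the Hdac1 island, and bases covered within 100 kb.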

Results

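Chromatin immunoprecipitation followed by sequencing was carried out on nephron progenitor cells, the fetal kidney cells that give rise to the epithelium of the nephron. Wild-type mouse embryos (E16.5) were the source of the cells, which were cultured before crosslinking. There was 1 library with an antibody against Hdac1 and 1 with an antibody against Hdac2, the class I histone deacetylases that act as catalytic subunits of the Sin3, NuRD and CoREST corepressor complexes. The files hold islands, stretches of mm10 in which the authors' caller found more reads than in background, each with a p-value or q-value of the authors. With no replicate for either antibody, every difference below compares these 2 libraries, no p is given between them, and 95% Wilson intervals cover counting error only. The read depth of the libraries is unknown.

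The strongest Hdac1 islands at gene ends included those over the 4 Hox clusters. An island of 89.4 kb on chromosome 11, from 96268001 to 96357400, ran across Hoxb9 to Hoxb2, members of the homeobox clusters that set position along the body axis. Islands of 64.0 kb, 47.4 kb and 42.2 kb lay over the Hoxc, Hoxa and Hoxd clusters, and islands of 29.6 kb and 22.0 kb lay over Nr2f2, an orphan nuclear receptor gene, and Bahcc1. All of these were listed at 0, the lowest value the files hold. The same Hox sequence carried Hdac2 islands that were shorter and separate, such as one of 13.8 kb over Hoxd8 and Hoxd9, within 1 kb of an end of Hoxd10, with a value of 2.25e-73. The strongest Hdac2 islands at gene ends lay elsewhere, at Gas8 (87.4 kb), Mid1 (53.2 kb), Fcgr3 (22.8 kb) and Adgrl1 (6.8 kb) and at runs of predicted genes such as Gm36327, Gm40363, Gm15319, Gm13275 and Gm13272. The Gas8 island lay wholly outside the gene, starting within 1 kb of its end. Of the 20 strongest Hdac2 islands, 8 were at a gene end. Gas8, Mid1, Gm36327 and Fcgr3 were also among the 10 genes with the strongest Hdac1 islands.

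In all, the Hdac1 list held 30182 islands over 69.0 Mb and the Hdac2 list 20307 islands over 65.5 Mb. Hdac1 islands had a median width of 2.0 kb (interquartile range 1.4 to 2.8 kb), and Hdac2 islands a median of 2.8 kb (2.0 to 4.0 kb). The authors' value was lower for Hdac1, with a median of 1.11e-16 and 82 islands at 0, than for Hdac2, with a median of 1.96e-08 and 8 islands at 0. These values depend on depth and background, so they rank islands within a list and do not measure binding between lists. Several of the strongest islands outside the Hox clusters had the same outline in both lists: the Gas8 island spanned 123537201 to 123624600 on chromosome 8 in each, and the Fcgr3 island spanned 171063601 to 171086400 on chromosome 1 in each. Among the 20 strongest Hdac2 islands, 12 had an Hdac1 island with both edges within 400 bp, against 27.7% of the 12061 Hdac2 islands that overlapped Hdac1; only 4 of the 20 strongest Hdac1 islands had an Hdac2 island with such edges. Both comparisons were chosen after the values were seen. Islands among the 20 strongest for Hdac2 ended at 124802400 on chromosome 14, 145341600 on chromosome 7 and 90602800 on chromosome 18. No gene or island lay farther along these chromosomes. Another began at 3000401 on chromosome 9, the first position of any gene or island there. Whether these islands, or those with the same outline in both lists, mark deacetylase binding was not tested.

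At Six2, the transcription factor gene that keeps nephron progenitors undifferentiated, both antibodies gave a broad island over the same gene end. The annotated gene spans 85662736 to 85688254 on chromosome 17. The Hdac1 island of 17.4 kb ran from 85679401 to 85696800 and was listed at 0, and the Hdac2 island of 18.2 kb ran from 85679801 to 85698000 with a value of 4.76e-26. Outside the gene, an Hdac1 island of 3.2 kb at a distance of 58.7 kb and an Hdac2 island of 2.8 kb at 59.3 kb overlapped each other, with values of 2.33e-66 and 1.45e-31. Within 100 kb of the gene there were 8 Hdac1 islands and 3 Hdac2 islands.

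**Figure D1:**
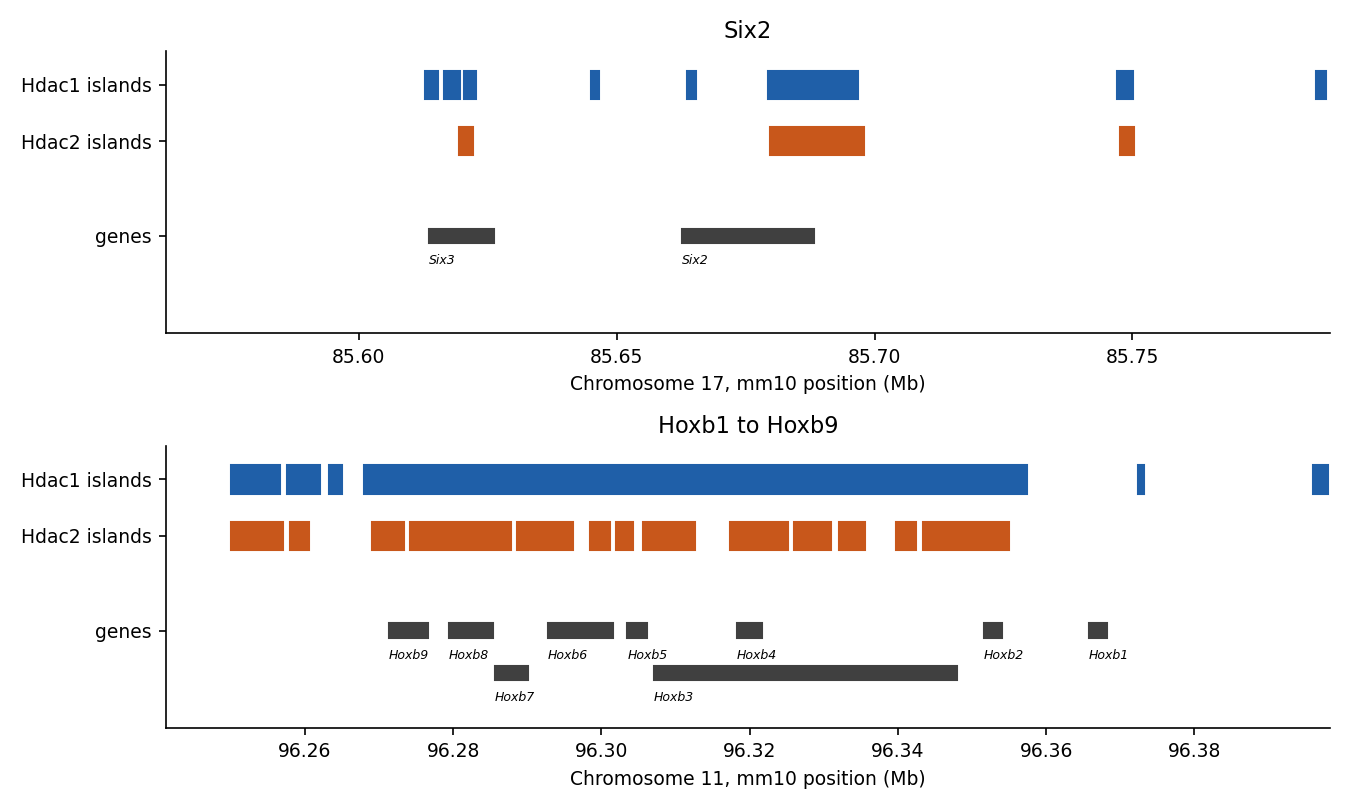
Maps of the Six2 region on chromosome 17 (upper) and the Hoxb region on chromosome 11 (lower), with mm10 position in Mb on the x axis, Hdac1 islands in blue, Hdac2 islands in orange and annotated protein-coding genes in dark grey. Broad islands of 17.4 kb (Hdac1) and 18.2 kb (Hdac2) cover the right end of Six2, and the 89.4 kb Hdac1 island over Hoxb9 to Hoxb2 faces several shorter Hdac2 islands.

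The next comparison asked how far the deacetylases shared their sites. Shared regions included Six2, Sall1, Wt1, Osr1 and Eya1 among progenitor regulators. The islands at Ing2, a Sin3 complex subunit gene, Stat6, Trmt61a, Bop1 and Cdca5 were the strongest at genes with Hdac1 and no Hdac2 at an end. That rule looks at gene ends only and does not exclude an Hdac2 island farther along such an island. For Ing2, no Hdac2 island lay within 100 kb. In total, 12024 Hdac1 islands (39.8%, interval 39.3 to 40.4%) overlapped an Hdac2 island by at least 1 bp, and 12061 Hdac2 islands (59.4%, interval 58.7 to 60.1%) overlapped an Hdac1 island. The lists shared 24.9 Mb, a Jaccard index of 0.227. When the Hdac1 islands were placed at random within their chromosomes 1000 times, between 1133 and 1355 overlapped Hdac2, so the observed number was 9.73 times the random mean. Random placement of the Hdac2 islands gave 1091 to 1306 overlaps, against a mean of 1202. The background library behind each list is not given in the sources used here, and if it was the same, part of the overlap may come from it. The random placements did not leave out assembly gaps or keep GC content, which may raise both ratios.

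Overlap followed the strength of the Hdac1 islands. In the strongest decile 85.2% overlapped Hdac2, in the fifth decile 41.8%, in the ninth 13.5% and in the weakest 18.3%. The share at a gene end fell with it, from 88.2% to 9.18%. For Hdac2 islands the overlap fell and rose again: 84.9% of the strongest decile overlapped Hdac1, 51.2% of the fifth and 65.4% of the weakest, and the share at a gene end was 40.8%, 23.8% and 38.1% in the same deciles.

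**Figure D2:**
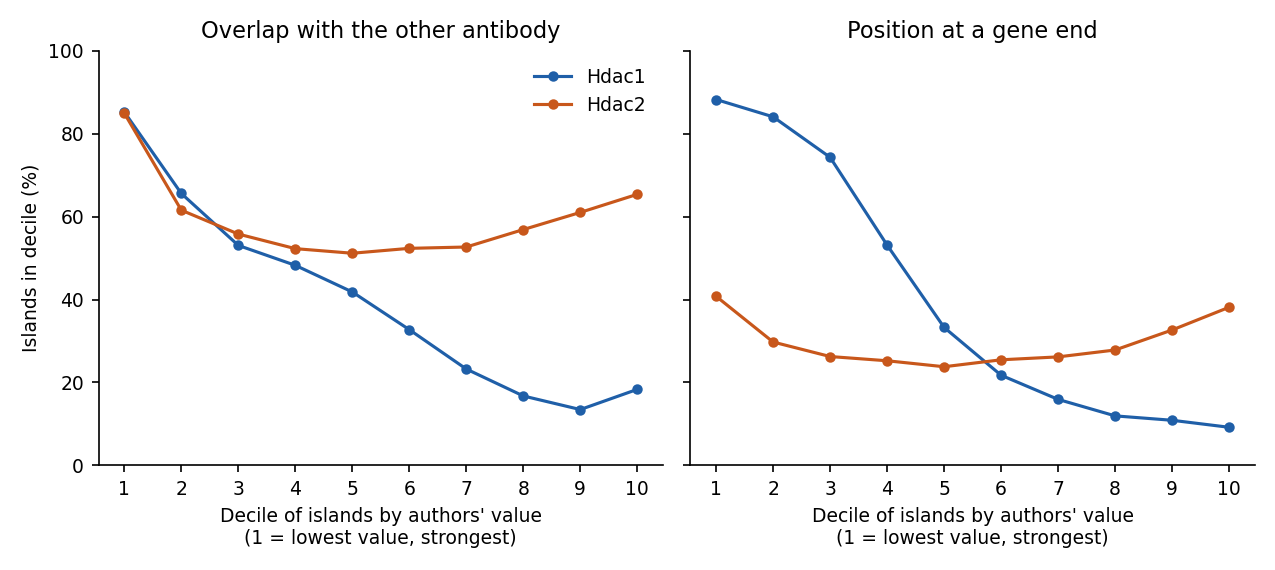
Percent of islands (y axis) that overlap an island of the other antibody (left) or lie within 1 kb of a protein-coding gene end (right), by decile of the authors' value within each list (x axis, 1 the strongest), with Hdac1 in blue and Hdac2 in orange. Overlap of Hdac1 islands falls from 85.2% to 13.5% in decile 9 and is 18.3% in decile 10, while Hdac2 overlap is lowest in decile 5 at 51.2%.

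Islands at gene ends were more common among those shared by the libraries than among those of Hdac2 alone, most of which lay outside genes. A gene end here is the 1 kb on either side of the first or last base of an annotated protein-coding gene, because the annotation used has no strand and so does not tell the transcription start from the other end. Of all Hdac1 islands 40.3% (interval 39.7 to 40.8%) lay at a gene end, 31.0% inside a gene only and 28.7% outside genes. Random placement put 5.83% at gene ends on average. Of Hdac2 islands 29.6% (interval 29.0 to 30.2%) lay at a gene end, 24.4% inside a gene only and 46.0% outside, against a random mean of 6.90% at gene ends.

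The 8246 Hdac2 islands with no Hdac1 overlap were broader, with a median of 3.8 kb, and 195 of them (2.36%, interval 2.06 to 2.72%) were at a gene end. This was below all 200 random placements of the same islands that also avoided Hdac1 islands, which had a mean of 5.57%. They were also less often inside genes (22.0%, against 33.1 to 36.0% in those placements), and 75.6% lay outside genes. Hdac1 islands without Hdac2 were different in this respect: 34.8% of the 18158 were at a gene end, against a mean of 5.02% in random placements that avoided Hdac2 islands. Shared Hdac2 islands were at a gene end in 48.2% of cases.

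At the level of genes, Hdac1 islands took in nearly all genes that had an Hdac2 island. Of 21883 protein-coding genes, 13283 (60.7%) had an Hdac1 island at an end and 6942 (31.7%) an Hdac2 island. Both were present at 6724 genes, which is 96.9% of the Hdac2 genes and 50.6% of the Hdac1 genes, where independent lists of these sizes would share 4214. At 246 of the 6724 genes (3.66%) the strongest Hdac1 and Hdac2 islands at the gene's ends did not overlap, among them the listed genes Bax, Cdc6, Cdk2, Cdkn1b, Hmg20b, Hoxa3, Neurod1, Rb1, Rpl4 and Rps18. There were 6559 genes with Hdac1 only, led by Ing2 (3.8 kb, 1.21e-278), Stat6 (8.8 kb, 3.14e-253) and Trmt61a (1.8 kb, 1.52e-249). The Stat6 island lay wholly outside the gene, starting within 1 kb of its end. The 218 genes with Hdac2 only were led by Gm21119 (97.6 kb, 2.1e-122), Gm21083 (92.2 kb, 6.47e-83), 4930467E23Rik (48.0 kb, 5.94e-75), Gm51573 and Gm9758. All of these carry provisional symbols. Here too the rule looks at gene ends and does not exclude Hdac1 farther along such an island. Hdac1 islands covered 58.3% of the 4930467E23Rik island and 30.8% of the Gm51573 island. The Gm21083 island overlapped 1 Hdac1 island, of 2 kb. The Gm21119 and Gm9758 islands overlapped no Hdac1 island. Neither protein had an island at 8382 genes. Keeping the upper 50% of each list by value reduced the Hdac2 genes to 3448 and the genes with both to 3277, and a 5 kb window raised the genes with Hdac2 only to 411.

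The stronger the Hdac1 island at a gene, the more often Hdac2 was there too. In the decile of genes with the strongest Hdac1 islands 88.5% had an Hdac2 island, against 11.7% in the weakest. Genes on the X chromosome stood apart. There, 25 of 338 genes with an Hdac1 island (7.40%, interval 5.06 to 10.7%) also had an Hdac2 island, compared with 51.7% (interval 50.9 to 52.6%) over the autosomes, where chromosome 7 had the lowest share at 46.0% and chromosome 3 the highest at 56.5%. The few X-linked genes with both included Cited1, a marker of uncommitted progenitors, and Rbbp7, a histone-binding subunit of deacetylase complexes. Hdac1 islands on X were weaker as well, with a median value at genes of 1.16e-27 against 6.00e-52 on the autosomes.

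**Figure D3:**
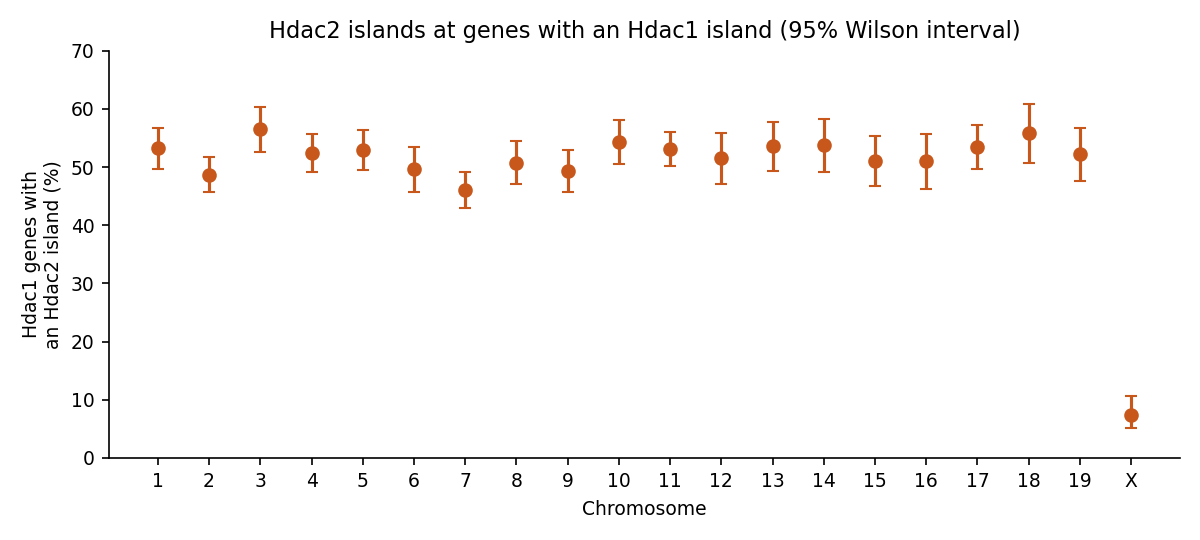
Percent of genes with an Hdac1 island at an end that also had an Hdac2 island (y axis), by chromosome (x axis), with 95% Wilson intervals as error bars; chromosome Y, with 1 such gene, is left out. The autosomes lie between 46.0% and 56.5%, and the X chromosome is at 7.40%.

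The gene lists asked which genes of the progenitor state and of neighbouring fates had islands. All 29 progenitor genes in the annotation had an Hdac1 island at an end and 25 had an Hdac2 island. Islands at these genes were broad for Hdac1, with a median of 8.0 kb against 2.4 kb over all Hdac1 genes, and 8 were listed at 0, among them Six2, Sall1, Eya1, Gdnf and Gas1. Sall1, a zinc finger regulator of kidney formation, had 16.4 kb for Hdac1 and 12.2 kb for Hdac2 (1.12e-45). Wt1, the Wilms tumour gene, had 13.0 kb (1.06e-309) and 7.8 kb (4.4e-12), and Osr1 had 8.0 kb (1.48e-61) and 1.4 kb (1.14e-06). The 4 without an Hdac2 island at an end were Pax2, Meox1, Crym and Rspo3, although an Hdac2 island of 7.4 kb (1.06e-13) lay inside Pax2, overlapping the 15.2 kb Hdac1 island at its end.

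Random lists matched on gene length gave a median of 19 genes with Hdac1 and 10 with Hdac2. The counts of the progenitor list exceeded those of all 10000 lists, a percentile of 100 for each library. This was not particular to progenitor genes. The ribosomal protein, proliferation, deacetylase complex and Hox lists were also at 100 for Hdac1, and the last 2 of these for Hdac2. Random genes came from all genes tested and were not matched on CpG content. Against random genes in the same deciles of Hdac1 island value, the 25 progenitor genes with Hdac2 were at percentile 96.3. This lay inside the central 95%, so the high Hdac2 count was not kept under this matching. Below, equal Hdac1 islands and equal strength mean this match by decile, which leaves island width unmatched. These percentiles describe the 2 libraries, since genes are not replicates. Hoxa11, Hoxc11 and Hoxd11 on this list lie on cluster islands that they share with other Hox genes.

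Genes of the next step, the committed cells that form the renal vesicle, had islands at more genes than random lists did. Of 28 genes, 25 had Hdac1 (percentile 99.9, random median 18) and 16 had Hdac2 (percentile 99.5, random median 9). Against genes with equal Hdac1 islands, which gave a median of 11, the 16 were at percentile 99.0. Wnt4, the signal that drives the transition to epithelium, had islands of 1.4 kb for Hdac1 (2.03e-85) and 1.8 kb for Hdac2 (6.22e-10). Lhx1, Jag1, Notch1, Notch2 and the Notch target Hes1 had both, with Hes1 listed at 0 for Hdac1 and at 4.8e-66 for Hdac2. Pax8, Fgf8, Hes5, Heyl, Irx1, Irx2, Pou3f3, Cdh1 and Osr2 had Hdac1 alone, and genes with neither included Hnf4a and Cdh6. Counted as bases covered within 100 kb, the list was at percentiles 48.8 and 41.7, in the middle of random lists, and with the upper 50% of islands the Hdac1 percentile was 95.8.

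Genes of mature nephron cells were mostly free of islands at their ends. Of 16 podocyte and tubule genes, 3 had Hdac1, fewer than in all 10000 random lists (percentile 0, random median 11), and 2 had Hdac2 (percentile 1.90). Podxl, which encodes the podocyte sialomucin podocalyxin, and Lrp2, the megalin gene, had both; Ptpro had Hdac1 alone. No island lay at an end of Nphs1, a slit diaphragm gene, or of Umod, Aqp1 and the transporter genes Slc34a1, Slc12a1, Slc12a3, Slc22a6 and Slc5a2. Counted as bases covered within 100 kb the percentiles were 14.0 and 44.4, inside the range of random lists. The low Hdac2 count also came inside it with the upper 50% of islands (25.4), islands anywhere in the gene or within 5 kb (8.47), unmatched random lists (4.97) and, on the 3 genes with Hdac1, lists matched on the Hdac1 island (86.6).

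Markers of other cells in the kidney were near or below the random level. Ureteric bud genes had Hdac1 at 16 of 20 (percentile 90.5) and Hdac2 at 8 (percentile 72.9), with both at Ret, Gfra1, Wnt7b, Etv4 and Etv5 and neither at Gata3, Krt8, Tfap2a and Tfap2b. Stromal genes had 15 and 8 of 20 (percentiles 76.6 and 63.5). Meis1, Meis2, Foxd1 and Tcf21 had both, and the collagen genes Col1a1 and Col1a2 had Hdac1 alone. Endothelial and blood genes had Hdac1 at 7 of 16 (percentile 5.49) and Hdac2 at 1, Erg (percentile 0.515), a low count that was lost under 4 alternatives, among them bases covered within 100 kb (89.1) and genes with equal Hdac1 islands (20.2). Genes of distant lineages, such as liver, muscle and neurons, had Hdac1 at 15 of 30 (percentile 24.5) and Hdac2 at 4 (percentile 2.66). The 4 were Neurod1, Neurog2, Olig2 and Snap25, with the Neurog2 island in the weakest decile of Hdac2 islands (0.0115). With the upper 50% of islands the Hdac1 percentiles of these last lists fell to 0.140 and 0.210, and by bases covered within 100 kb the Hdac2 percentile of the distant lineages was 0.0700. It was also lower against random lists not matched on length (1.21) and for islands in a gene or within 5 kb (0.625), and higher with the upper 50% of islands (13.3) and against genes with equal Hdac1 islands (67.3).

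**Figure D4:**
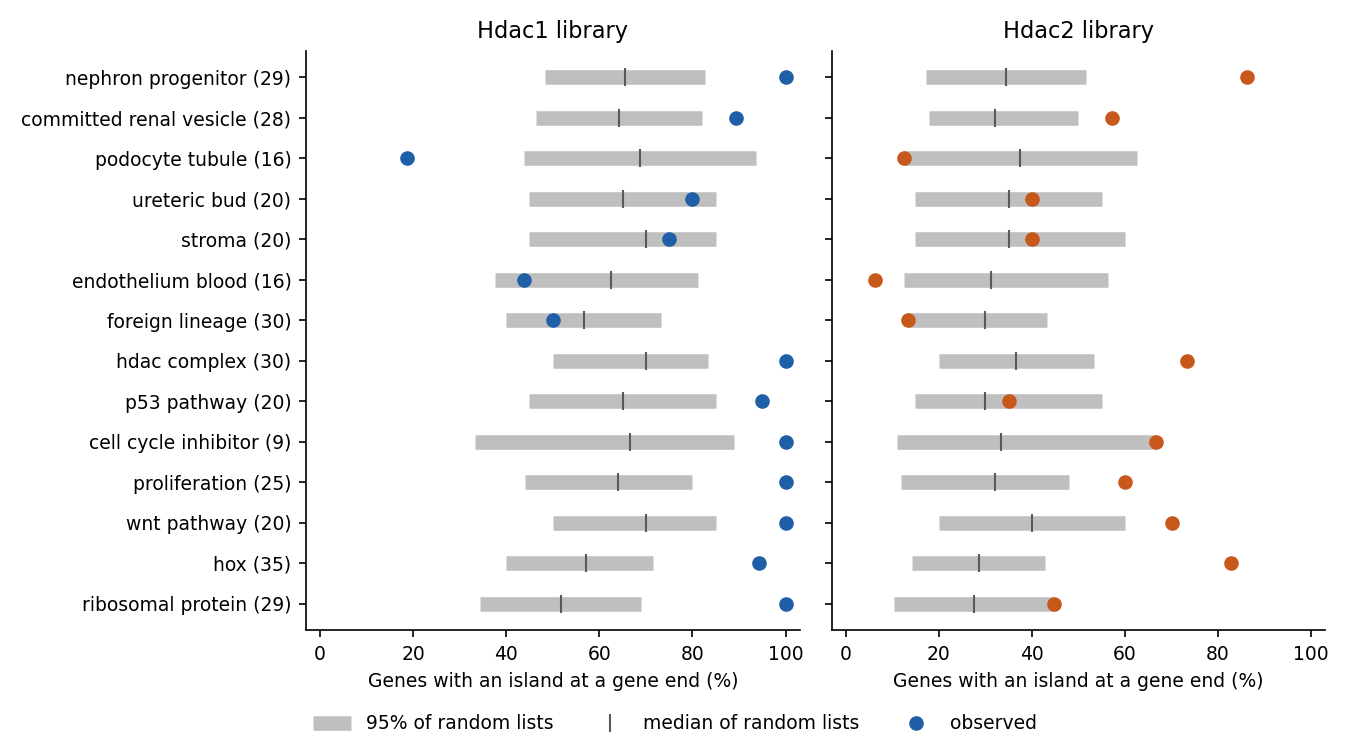
Percent of the genes of each list with an island at a gene end (x axis) for the Hdac1 library (left, blue dots) and the Hdac2 library (right, orange dots), with the number of genes in parentheses; grey bars span the central 95% of 10000 random lists matched on gene length and ticks mark their median. Progenitor genes reach 100% for Hdac1 and 86.2% for Hdac2, while podocyte and tubule genes are at 18.8% and 12.5%.

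Islands of both proteins lay at the deacetylases' own genes and those of their partners. All 30 genes for class I deacetylases and their partner proteins, most of them in the Sin3, NuRD and CoREST complexes, had an Hdac1 island (percentile 100) and 22 had an Hdac2 island (percentile 100). At Hdac1 itself the islands measured 3.8 kb for Hdac1 (1.74e-168) and 2.2 kb for Hdac2 (1.3e-06), and at Hdac2 2.4 kb (1.25e-88) and 1.4 kb (1.51e-12). The Hdac2 island at the Hdac1 gene lay wholly outside that gene, within 1 kb of an end. Sin3a, Sap30, Chd3, Chd4, Rcor1 and Phf21a had both, while Sin3b, Sap18, Mta1, Mta2, Gatad2a, Kdm1a, Ing2 and Mideas had Hdac1 alone. Among genes with Hdac1 islands of equal strength, the Hdac2 count was at percentile 44.6, and by bases covered within 100 kb the list was at 90.8 for Hdac2.

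Cell cycle and p53 genes nearly all had Hdac1. All 25 proliferation genes had Hdac1 and 15 had Hdac2 (percentiles 100 and 99.9). Mki67, Ccna2, Aurka, Plk1 and Pcna had both, and Top2a, Ccnb1, Cdk1, Mcm2 and Mcm3 had Hdac1 alone. Their Hdac1 islands were strong, with a median of 3.94e-124, and against genes with equal Hdac1 islands the 15 with Hdac2 were few, at percentile 2.27 with a random median of 19. With the upper 50% of islands the Hdac2 percentile was 93.3, and by bases covered within 100 kb the list was at 86.0 (Hdac1) and 48.8 (Hdac2). Of 20 genes of the p53 pathway, which halts the cell cycle or starts cell death on DNA damage, 19 had Hdac1 (percentile 99.9) and 7 had Hdac2 (percentile 60.9, or 9.38 against genes with equal Hdac1 islands, with a random median of 10). Trp53, Mdm2 and Bbc3 had both, and Bax had them at opposite ends. Cdkn1a, the gene of the inhibitor p21, had Hdac1 alone (4.8 kb, 5.2e-50), and Mdm4 had neither. The Hdac2 islands counted at Bax (0.00764) and at the proliferation gene Cdk2 (0.0166) lay wholly outside the genes. Both were in the weakest decile of Hdac2 islands. All 9 cell cycle inhibitor genes had Hdac1 (percentile 99.2), and 6 had Hdac2 (percentile 97.7, or 35.2 against genes with equal Hdac1 islands). The 3 without Hdac2 were Cdkn1c, Cdkn2b and Rbl2. By bases covered within 100 kb the p53 list was at 80.4 for Hdac1, and the inhibitors at 65.4 (Hdac1) and 58.0 (Hdac2). The inhibitors' Hdac2 percentile was 88.7 with the upper 50% of islands and 90.5 with islands anywhere in the gene or within 5 kb.

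All 20 Wnt pathway genes had Hdac1 (percentile 99.99) and 14 had Hdac2 (percentile 99.8). Ctnnb1, which encodes beta-catenin, had islands of 3.8 kb (3.98e-153) and 3.0 kb (3.78e-23), and Myc, Lgr5, Tcf7l2 and the Frizzled receptor genes Fzd1, Fzd2 and Fzd7 had both as well. Axin2, Dkk1, Rnf43, Znrf3, Apc and Lrp5 had Hdac1 alone, and the Rnf43 island lay wholly outside the gene. Against genes with equal Hdac1 islands the Hdac2 count was at percentile 64.6, and by bases covered within 100 kb the list was at 97.4 (Hdac1) and 89.6 (Hdac2).

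Of 35 Hox genes other than the progenitor list's, 33 had Hdac1 and 29 had Hdac2 (percentile 100 for each). The 33 genes rested on 13 Hdac1 islands and 23 of them on islands listed at 0, so they are not independent. Hoxb1 and Hoxb13 had neither, and Hoxc4, Hoxc12, Hoxc13 and Hoxd13 had Hdac1 alone. Without islands wider than 20 kb, which removes the cluster islands, the Hdac1 percentile was 1.39. Against genes in the same deciles of Hdac1 island value the Hdac2 count was at percentile 99.0. Those genes did not have equal islands in width. The Hox genes' Hdac1 islands had a median of 47.4 kb, against 4.0 kb in the strongest decile of genes. This percentile therefore does not show more Hdac2 than at like Hdac1 islands.

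Ribosomal protein genes, which every growing cell transcribes, served as a list without a link to kidney fate. All 29 had Hdac1 (percentile 100), with a median island of 3.0 kb, and 13 had Hdac2 (percentile 97.7). Rpl3, Rpl7 and Rpl10a had both, and Rpl8, Rpl11, Rps3 and Rpsa had Hdac1 alone. Against genes with equal Hdac1 islands the 13 were few, at percentile 1.31 with a random median of 19, and with the upper 50% of Hdac2 islands the list was at percentile 17.8. Unmatched random lists gave 92.6 for Hdac2, and islands anywhere in the gene or within 5 kb gave 89.3.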

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

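The placements that avoid the other antibody's islands, the shifted lists, the islands up to 20 kb, the bases covered within 100 kb and the matching on the Hdac1 island were chosen after the results were seen. No paired analysis was possible because each antibody had 1 library, and for the same reason no library could be left out. The planned GC-matched placement, exclusion of assembly gaps, CpG-matched lists, exon and intron split and motif alternatives were not run, since neither genome sequence nor gene models were used. Of the values that answer a comparison, 47 stayed and 22 moved. Stayed does not mean unchanged: with equal list lengths the genes with Hdac2 only went from 218 to 312 and counted as stayed. A share of overlap going from 39.8% to 36.0% counted as moved. Of the list percentiles, 129 kept their place inside, above or below the central 95% of random lists, and 5 left it. Another 34 above or below it came inside or changed side, 11 of these past percentile 50. Overlap was 9.20 times random for Hdac1 and 9.48 times for Hdac2 when lists were shifted as a whole.

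With the upper 50% of islands, which shortens the lists by construction, there were 15091 Hdac1 islands (41.3 Mb) and 10153 Hdac2 islands (34.8 Mb). Overlap was 33.8% of Hdac1 and 50.8% of Hdac2 islands, 66.6% of Hdac1 islands were at a gene end, 3448 genes had Hdac2, 3277 had both, 5 Hdac2 lists were above the limit in place of 8, and the ribosomal Hdac2 percentile was 17.8. Asking for 50% of the island gave 34.2% and 54.4% overlap, the island's midpoint 36.0% and 55.0%, and equal list lengths 51.1% and 51.8%, for Hdac1 and Hdac2 in turn. A 5 kb window, wider by construction, put 48.4% of Hdac1 and 35.8% of Hdac2 islands at a gene end and gave 411 genes with Hdac2 only.

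Counting bases covered within 100 kb left 4 Hdac1 lists and 3 Hdac2 lists above the limit, in place of 9 and 8. The committed list went to percentiles 48.8 (Hdac1) and 41.7 (Hdac2), proliferation to 48.8 and endothelium and blood to 89.1 for Hdac2. Matching on the Hdac1 island left 2 Hdac2 lists above the limit and brought progenitor (96.3), Wnt (64.6), endothelium and blood (20.2), podocyte and tubule genes (86.6), deacetylase complexes (44.6) and cell cycle inhibitors (35.2) inside the central 95%; proliferation (2.27) and ribosomal proteins (1.31) went below it. Without islands over 20 kb the Hox list fell to 1.39 for Hdac1, because the cluster islands were removed; for the other percentiles given here and for the overlap under other definitions the cause was not tested.

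Unknown read depth limits the lists: an island missing from the Hdac2 list, whose values were weaker, does not show that Hdac2 was absent.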

Other observations

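All tests and comparisons in this part were chosen after the values they measure had been seen, except the comparison of X-linked genes with matched autosomal genes. The test of neighbouring genes replaced an earlier test of shared island edges, which was circular; its values stand with the strongest islands. The test of Hdac2 density outside genes replaced an earlier one on islands without Hdac1, because choosing those islands influences their density on a chromosome poor in Hdac1. Its criterion was also changed after its value was known: it first asked whether the density on X was below that of the autosomes, which it was, and now asks whether it was low enough to be the whole cause. The test of neighbouring genes was changed likewise, to keep 1 gene per island.

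Among genes with an Hdac1 island, groups of genes with a shared symbol differed in how often Hdac2 was there too. Mediator subunit genes (Med) had Hdac1 at 29 of 30 and Hdac2 at 8 of those 29, where genes with equal Hdac1 islands gave a median of 17 (percentile 0.0150). Centrosomal protein genes (Cep) had 14 of 35 against 22 (percentile 0.265), general transcription factor genes (Gtf) 7 of 22 against 13 (0.510), DEAD-box helicase genes (Ddx) 12 of 32 against 18 (0.680) and mitochondrial ribosomal protein genes of the large subunit (Mrpl) 19 of 48 against 26 (1.33). The other groups at or below 2.5 were Rnf with 28 of 64 against 37 (0.485), Cfap with 5 of 24 against 10 (1.64), Tmem with 73 of 186 against 85 (1.75) and Sec with 9 of 24 against 14 (2.42). Zinc finger genes of the Zbtb group had 31 of 38 against 26 (97.4), and solute carrier genes (Slc) 121 of 244 against 107 (97.7). Of 80 groups with a percentile, 9 were at or below 2.5 and 1, Slc, was above the central 95%, where chance gives 4 outside it in all; the upper side thus held no more groups than chance gives, and Zbtb lay inside the limit.

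Receptor gene clusters had almost no islands at gene ends. Of 1110 olfactory receptor genes (Olfr) 3 had Hdac1 and 6 had Hdac2, and of 355 vomeronasal genes (Vmn) 2 and 4. The major urinary protein genes (Mup), a cluster of near-identical copies, differed from them: 10 of 22 had an Hdac2 island and 0 of 22 an Hdac1 island.

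Genes on X with an Hdac1 island seldom had Hdac2, 25 of 338. Weaker Hdac1 islands on X cannot be the whole cause: autosomal genes with Hdac1 islands of equal strength gave a median of 117 with both and never fewer than 90 in 10000 draws. Hdac2 calls were not lacking evenly on X. Per Mb outside genes, Hdac2 islands were 0.797 times as dense on X as on the autosomes (interval 0.733 to 0.866), while the 25 genes were 0.214 times the matched median. However, only 64 of the 736 Hdac2 islands on X overlapped Hdac1, so most of those outside genes were of the kind without Hdac1. The test thus cannot decide whether calls of the kind shared with Hdac1 were evenly few on X, and a lack of such calls stays open. Over the whole chromosome the ratio was 0.539 for Hdac2 islands, a mixture of 0.0760 for the 64 on X that overlapped Hdac1 (interval 0.0585 to 0.0971) and 1.28 for the 672 that did not, and it was 0.225 for Hdac1 islands, whose scarcity lowers the first of these and raises the second. No biological explanation was tested, and the antibodies, their amounts and the background libraries stay open with 1 library each.

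Hdac2 islands without Hdac1 lay away from genes. Random placements that also avoided Hdac1 put a mean of 5.57% at gene ends, all 200 of them more than the 2.36% observed, which argues against calls scattered at random. Being only the weakest calls by the authors' value was argued against too. Of the 3946 in the upper 50% of the Hdac2 list by that value, 2.15% were at a gene end, where such placements gave a mean of 5.79%. The test cannot speak for calls that are weak by fold or read number, since the lists hold neither. Base composition, mappability and the background library stay open, because neither sequence nor reads were used, and no biological explanation was tested.

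Genes with Hdac2 and no Hdac1 at an end were often predicted genes with Gm numbers, 93 of 218 (42.7%). This compared with 2.45% of the genes with both and 12.4% of all 8600 genes without Hdac1. Clusters of near-identical copies, where reads of several copies fall on few, are a candidate explanation: 124 of the 218 had another such gene within 1 Mb (random sets of genes without Hdac1: 56 to 91 in 95% of draws), and with 1 gene kept for each of their 201 islands, since genes on 1 island are neighbours by construction, 105 did (48 to 81). The islands were long, with a median of 4.2 kb. Broad Hdac2 signal over gene-poor regions would give neighbours as well, so the test leaves both open.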
